A study of Mus musculus with 6 samples.

How the data were processed

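RNA sequencing of Lgr5-EGFP-high intestinal stem cells was analysed from gene counts in 6 libraries, 3 labelled control and 3 labelled Klf5-KO. Per the labels' protocols, mice of the C57BL/6 strain received 1 mg of tamoxifen on each of 5 days, crypts of the proximal small intestine were released with 5 mM EDTA, cells were dissociated for 45 minutes and sorted, and stranded libraries were made from total RNA after removal of ribosomal RNA. The labels give no day, litter or sequencing batch.

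The deposited values are whole-number read counts per gene, not normalized. Per the submitters' processing notes, reads were aligned with STAR 2.5.2a to mm10, and DESeq2 1.18.1 is also named there. Per the file headers, the authors counted with featureCounts 1.4.3-p1 on GENCODE vM16 with the reverse strand setting, so reads of a gene and of its antisense partner were counted apart. The command in the headers has no option for read pairs, for reads mapped to several places or for reads over several genes. Genes with near-identical copies, such as alpha-defensins, and genes that share exons on 1 strand are therefore uncertain. Each count sums all exons of a gene and cannot tell floxed exons of Klf5 from the rest. In the file of control replicate 1, the strand text of 4 gene rows differed from that in the file of control replicate 2, and the gene order was the same.

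Gene IDs were given symbols and biotypes from GENCODE vM21, which matched 53274 of 53379 IDs; coordinates are those of the files (mm10). Counts were tested with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr, which left 19339, libraries were scaled with TMM factors, and the 2 groups were compared by the quasi-likelihood F test with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The SE of a log2 fold change is its size over the square root of F. CPM values use the TMM-scaled library sizes. The biological coefficient of variation was 17.0%. No pair of libraries agreed within sampling noise (chi-square per degree of freedom of at least 43.3), so none was taken for a copy of another; this does not show that they came from separate mice. Depth was 61563625 to 77666540 counts; a count of 0 allows up to 0.0389 to 0.0484 CPM, taking 3 counts as the floor and covering counting error only. The genes Gm26917 and Gm42418, which hold ribosomal RNA-like sequence, took 13.5 to 18.3% of the counts.

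Before the data were examined, 37 gene lists were fixed from textbook knowledge (stem cell types, signalling, lineages, metabolism, other cell types and signs of RNA quality), and 35 of them were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. The sex-linked list served only to describe the libraries, and the erythrocyte list had fewer than 3 tested genes. Camera with an estimated correlation and fry were run beside it. With an estimated correlation, camera takes its degrees of freedom from the few libraries, so calls are hard to reach. The named genes were chosen by a rule fixed at the same time. It takes Klf5; the 8 largest rises and the 8 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups, leaving out provisional symbols; 13 genes of stem cells, lineage and cell cycle whatever their result; and for each list up to 3 called members with the smallest adjusted p, or the most abundant member where none was called. Not every gene so chosen is printed. Members named outside this rule, as the few exceptions to a list's direction, were chosen after their values were seen.

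The analysis was tested on simulated counts with 200 genes changed and 1 list raised, drawn from the means, dispersions and library sizes of these 6 libraries (18965 genes after the filter). The quasi-likelihood test recovered 16% of genes changed 1.5-fold, 55.1% at 2-fold, 95.9% at 4-fold and 100% at 8-fold, all with the right sign. The simulation changed far fewer genes than were called in the data (4994 of 19339). Adjusted p-values depend on that share, so these recoveries need not hold for the data. A stricter initial requirement on recovery was not met at 2-fold, and it was replaced by checks of signs, fold sizes and the raised list. Of its 152 calls 11 were unchanged genes (7.24%, above the nominal 5%), and with DESeq2 1.42.0 it was 33 of 198 (16.7%). The raised list was called and no other. The simulated genes varied independently of each other, so this does not show how often lists are called falsely where their genes move together.

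Alternatives set before the data were examined were RLE and upper-quartile scaling, removal of mitochondrial and structural non-coding RNAs, no filter or a CPM filter, DESeq2, limma-voom, robust dispersion, the replicate number as a block, stricter thresholds and leaving out each library. Added after seeing the data were a correction for GC content and gene length, sex as a covariate, removal of Gm26917 and Gm42418, and leaving out control replicate 3 and Klf5-KO replicate 2 together.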

Results

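Gene expression was measured by RNA sequencing in intestinal stem cells of adult mice, sorted from crypts of the proximal small intestine as the cells with the brightest green fluorescence from the Lgr5-EGFP reporter. Lgr5 is a receptor for R-spondins that marks the cycling stem cells at the crypt base. There were 3 control libraries and 3 libraries labelled Klf5-KO, from mice in which tamoxifen-activated Cre recombinase was used to delete Klf5, a zinc finger transcription factor of the Kruppel-like family. The deposited read counts per gene summed to 72246097, 77666540 and 61563625 in control replicates 1, 2 and 3 and to 66942102, 66431695 and 72240451 in Klf5-KO replicates 1, 2 and 3. The labels do not say whether each replicate was a separate mouse, so the p-values measure the spread between these libraries. The study's design sets Klf5-deleted against control stem cells, and the question is which transcripts differ between them.

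Klf5 itself was examined first, and its counts went against the labels. The gene (ENSMUSG00000005148.8, mm10 chromosome 14, 99298691 to 99315036, plus strand, 4 exon blocks) had 34951, 39455 and 33862 counts in control replicates 1, 2 and 3 and 60238, 58956 and 63492 counts in Klf5-KO replicates 1, 2 and 3. Klf5 was therefore higher in the libraries labelled Klf5-KO, at a normalised read count (CPM, counts scaled to the size of the library) of 891.7 ± 23.1 against 512.8 ± 33.1 CPM in the controls (SD, n = 3 each). The log2 fold change was 0.80 (SE 0.10, adjusted p = 6.3e-04, edgeR's quasi-likelihood test), and every Klf5-KO value lay above every control value. The exact Poisson 95% intervals of the counts cover counting error only. They ran from 34586 to 35319 in control replicate 1 and from 39067 to 39846 in control replicate 2, the highest control count. In Klf5-KO replicate 2, the lowest Klf5-KO count, the interval ran from 58481 to 59434. A count over the whole gene does not show which exons the reads came from, and the exons removed by Cre are not given in the sources used here. The count thus neither shows the deletion nor tells whether the group labels are right. Every direction below is that of the libraries labelled Klf5-KO relative to the libraries labelled control.

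**Figure D1:**
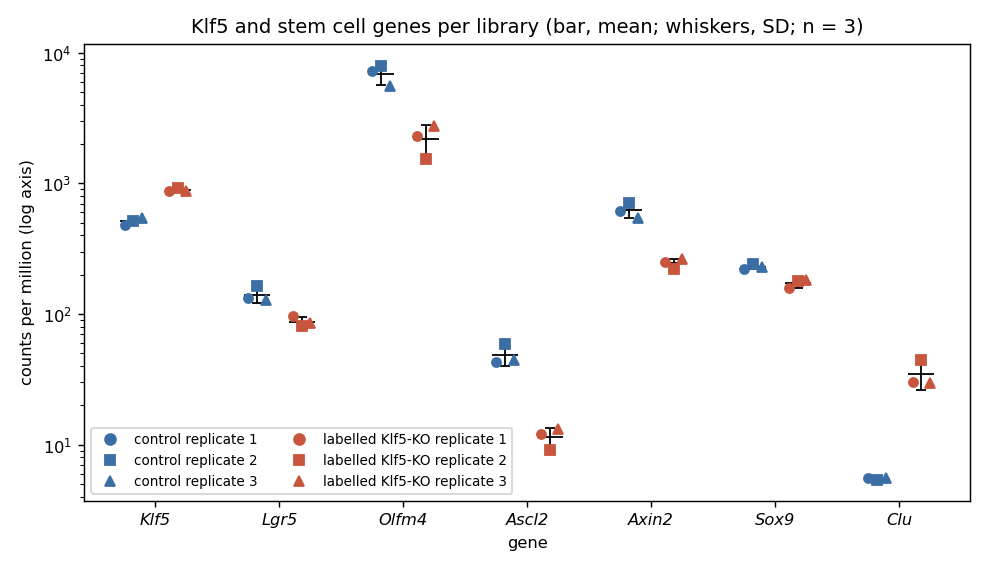
Normalised read counts (CPM, log axis) of Klf5 and of 6 genes of stem and revival cells in each library, with points for the libraries, horizontal bars for the mean and whiskers for the SD (n = 3 per group). Klf5 and Clu were higher in the 3 libraries labelled Klf5-KO, at means of 891.7 and 34.7, and Lgr5, Olfm4, Ascl2, Axin2 and Sox9 were lower, at 87.6, 2202, 11.4, 244 and 173.

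The groups differed widely. Of 19339 genes tested, 2581 were higher and 2413 were lower in the libraries labelled Klf5-KO at an adjusted p under 0.05 (edgeR), together 25.8% of the genes, and 1099 of the higher and 1144 of the lower genes changed at least 2-fold. The largest rise among well-measured genes was that of Reg1, a secreted lectin of the regenerating islet-derived family (chromosome 6, 78422711 to 78428667), from 15.3 ± 8.3 to 1032 ± 280 CPM (log2 fold change 6.08, SE 0.47, adjusted p = 5.1e-05). Its neighbours Reg3g and Reg3b, bactericidal lectins of the gut epithelium, rose by 4.46 (SE 0.71) and 4.45 (SE 0.87) on the log2 scale. The largest fall was that of Sfrp5, a secreted inhibitor of Wnt signalling (chromosome 19, 42197971 to 42202252), from 48.1 ± 8.4 to 2.32 ± 1.94 CPM (log2 fold change −4.36, SE 0.56, adjusted p = 7.1e-04).

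The other large rises were those of Prr5l (log2 fold change 5.73), the monocarboxylate and short-chain fatty acid transporter gene Slc5a8 (5.29), Thsd4 (4.98), the receptor tyrosine kinase gene Ros1 (3.96) and the cytochrome P450 gene Cyp2c55 (3.93). Slc5a8 (chromosome 10, 88885992 to 88929515) reached 68.0 ± 6.1 CPM in the libraries labelled Klf5-KO (SE of the log2 fold change 0.20, adjusted p = 1.3e-06). Besides Sfrp5, the largest falls were those of the proteoglycan gene Prelp (−4.27), the semaphorin gene Sema7a (−3.30), the cytochrome P450 gene Cyp2e1 (−3.21), the heparanase gene Hpse (−3.20), Lfng (−3.06), the angiopoietin gene Angpt2 (−3.05) and Gp1bb (−3.04). Gp1bb shares exons on its strand with Sept5, and reads that match several related Reg3 or Cyp2c genes could go uncounted. The values of Gp1bb, Reg3b, Reg3g and Cyp2c55 are therefore uncertain. Reg3b was unevenly measured, at 2006 ± 2025 CPM, and its call was lost with robust dispersion (adjusted p = 0.076).

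On the first principal component, which held 62.8% of the variance, the groups lay apart, at −46.4 to −55.4 for the controls and 48.4 to 55.5 for the libraries labelled Klf5-KO. Control replicate 3 stood apart on the second component (13.2% of the variance), at −46.9 against 26.3 and 22.0 in control replicates 1 and 2. Xist and Y-linked transcripts marked control replicate 1 and Klf5-KO replicate 3 as male and the other libraries as female. The gene counts moved by over 1.5 times without Klf5-KO replicate 1 (1605 higher and 1467 lower), without control replicate 2 (1689 higher), without Klf5-KO replicate 2 (1606 lower) and without Klf5-KO replicate 3 (1526 lower). With control replicate 3 and Klf5-KO replicate 2 both left out, 2576 genes were higher and 2352 lower.

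**Figure D2:**
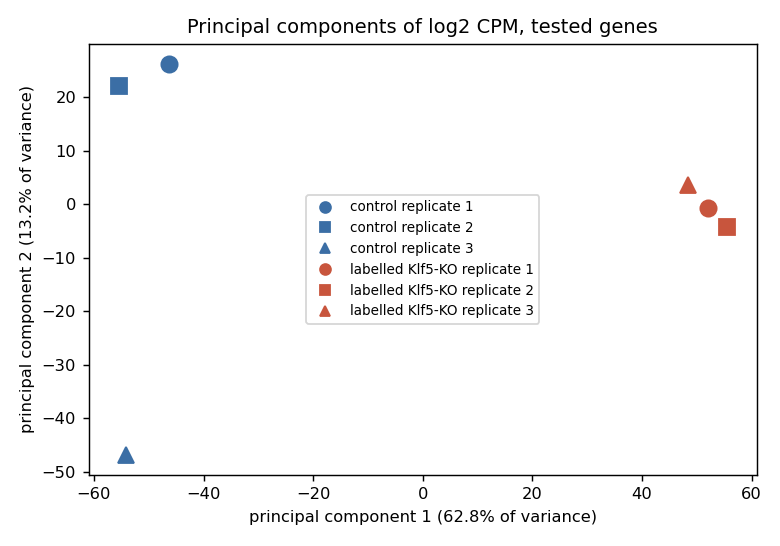
The first principal components of log2 CPM over the tested genes, with 1 point per library and the share of variance on each axis. The first component (62.8%) separates the 3 control libraries from the 3 libraries labelled Klf5-KO, and control replicate 3 lies at −46.9 on the second (13.2%), away from the others.

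Stem cell genes were lower in the libraries labelled Klf5-KO. Of 26 tested markers of intestinal stem cells, 17 fell and 2 rose, with the same counts adjusted over the list alone, and the median log2 fold change was −0.56 (adjusted p = 1.0e-08, camera with a preset correlation; adjusted p = 0.43 with an estimated correlation). Lgr5 fell from 140.8 ± 19.2 to 87.6 ± 8.2 CPM (log2 fold change −0.68, SE 0.11, adjusted p = 0.0027). The secreted glycoprotein gene Olfm4 fell from 6891 ± 1211 to 2202 ± 620 CPM (log2 fold change −1.65, SE 0.23, adjusted p = 0.0010), and Ascl2, a transcription factor that maintains stem cells, fell from 48.9 ± 8.6 to 11.4 ± 2.1 CPM (log2 fold change −2.10, SE 0.17, adjusted p = 5.5e-05). The sodium channel subunit gene Scn2b and the protocadherin gene Pcdh8 fell, with log2 fold changes of −2.39 and −1.53. Prom1 and Nrn1 rose. Among 9 markers ascribed to reserve stem cells, 6 fell and 2 rose, also adjusted over the list alone, and the list was not called by camera (adjusted p = 0.60), while fry called it (adjusted p = 0.0499). Those that rose were Hopx (log2 fold change 0.85) and Clu, which encodes clusterin and marks revival stem cells after injury. Clu rose from 5.51 ± 0.12 to 34.7 ± 8.5 CPM (log2 fold change 2.66, SE 0.17, adjusted p = 1.4e-05).

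Wnt targets fell as well. Of 19 tested targets of Wnt and beta-catenin signalling, 11 fell and none rose (11 and 2 adjusted over the list alone), with a median log2 fold change of −0.54 (adjusted p = 1.1e-07, camera; adjusted p = 0.43 with an estimated correlation). Axin2, a feedback inhibitor of the pathway, fell from 625 ± 84.5 to 244 ± 22.1 CPM (log2 fold change −1.36, SE 0.12, adjusted p = 1.1e-04). Ephb2 and Ephb3, receptors that position cells along the crypt, fell (log2 fold changes −1.09 and −1.57), as did the cyclin gene Ccnd1 (−1.78) and Sox9 (−0.42). Several of these, Lgr5, Ascl2 and Sox9 among them, were also on the stem cell list.

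Genes of the cell cycle were tested in 2 lists. Of 26 genes of DNA replication, 7 fell and 1, Pcna, rose (8 and 1 adjusted over the list alone), with a median of −0.20 (adjusted p = 0.035, camera; adjusted p = 0.75 with an estimated correlation). Cdt1, Mcm10 and Cdc6, which license replication origins or act at them, fell, with log2 fold changes of −0.61, −0.61 and −0.42. The call for this list was lost without control replicate 1 (adjusted p = 0.16), without control replicate 2 (0.096), without Klf5-KO replicate 2 (0.097) and with the GC and length correction (0.057). Of 25 genes of mitosis, 1 rose (Cdk1) and 1 fell (Kif23), with the same counts adjusted over the list alone and a median of −0.06 (adjusted p = 0.82, camera). Without control replicate 3 the mitosis list was called lower (median −0.18, adjusted p = 0.045; adjusted p = 0.65 with an estimated correlation). The Kif23 call was lost without control replicate 1 (adjusted p = 0.052) or Klf5-KO replicate 2 (0.067). Mki67, the gene of the proliferation antigen Ki-67, stood at 1103 ± 321 CPM in the controls and 799 ± 46.0 CPM in the libraries labelled Klf5-KO (adjusted p = 0.11). The Mki67 difference passed with DESeq2 (adjusted p = 0.038), with no low-count filter (0.012), and without control replicate 3 (log2 fold change −0.68, adjusted p = 0.0055). The cell cycle inhibitor gene Cdkn1a had a log2 fold change of −0.28 (adjusted p = 0.36).

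Lists of secretory lineage genes were called lower, apart from those of tuft and Paneth cells. Of 18 genes that specify secretory cells, 11 fell and none rose (12 and 0 adjusted over the list alone; median −0.80; adjusted p = 2.3e-06, camera; adjusted p = 0.43 with an estimated correlation). The transcription factor genes Hes6, Foxa2 and Sox4 fell, with log2 fold changes of −0.93, −1.19 and −0.57, as did the Notch ligand gene Dll4. Atoh1, the master regulator of secretory fate, fell from 12.4 ± 3.2 to 7.58 ± 1.48 CPM (log2 fold change −0.71, SE 0.20, adjusted p = 0.031). The Atoh1 call was lost without control replicate 2 (adjusted p = 0.077), control replicate 3 (0.079), Klf5-KO replicate 1 (0.12) or Klf5-KO replicate 3 (0.11).

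Of 23 enteroendocrine markers, 17 fell and none rose (19 and 0 adjusted over the list alone), and the median was −1.06 (adjusted p = 1.6e-07, camera; adjusted p = 0.43 with an estimated correlation). The transcription factor gene Fev and the ghrelin gene Ghrl fell, with log2 fold changes of −1.52 and −1.33. Of 18 goblet cell markers, 10 fell and 1, Tmsb10, rose, with the same counts adjusted over the list alone (median −0.82; adjusted p = 2.4e-05, camera; adjusted p = 0.43 with an estimated correlation). The trefoil factor gene Tff3 fell from 175 ± 21.9 to 63.6 ± 9.3 CPM, and Fcgbp, a component of mucus, fell from 1455 ± 279 to 523 ± 114 CPM. The summed CPM of the enteroendocrine markers in control replicate 3 was 369, against 194 and 220 in control replicates 1 and 2.

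The list of Notch pathway genes was called lower. Of 19 tested, 6 fell and 1, Rbpj, rose, with the same counts adjusted over the list alone; the median was −0.20 (adjusted p = 9.9e-04, camera; adjusted p = 0.43 with an estimated correlation). Lfng, a glycosyltransferase that modifies Notch receptors, fell from 54.4 ± 10.1 to 6.50 ± 1.16 CPM (log2 fold change −3.06, SE 0.17, adjusted p = 7.7e-06). Nrarp, a target of the pathway, and Notch1 fell, with log2 fold changes of −1.20 and −0.78.

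Tuft cell markers rose. Of 20 tested, 13 rose and none fell (16 and 0 adjusted over the list alone), with a median of 0.82 (adjusted p = 3.5e-06, camera; adjusted p = 0.65 with an estimated correlation). The kinase gene Matk rose from 7.28 ± 0.35 to 20.4 ± 5.7 CPM (log2 fold change 1.49, SE 0.19, adjusted p = 6.2e-04), and Rgs13 and Sh2d6 rose by 1.43 and 1.03 on the log2 scale. Of 25 enterocyte markers, 10 rose and 1, Enpep, fell (11 and 2 adjusted over the list alone), with a median of 0.64 (adjusted p = 9.4e-05, camera; adjusted p = 0.74 with an estimated correlation). Sis, the sucrase-isomaltase gene, rose from 76.3 ± 19.7 to 305 ± 84.7 CPM, and Mttp and Apob, which serve lipoprotein assembly, rose 2.47-fold and 2.39-fold.

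Paneth cell markers were not called in the main analysis, and control replicate 3 differed from the other controls. None of 16 tested markers passed, also when adjusted over the list alone; the median log2 fold change was 0.39 (adjusted p = 0.12, camera). Their summed CPM was 1766, 2131 and 20839 in control replicates 1, 2 and 3 and 9479, 9678 and 12002 in Klf5-KO replicates 1, 2 and 3. The alpha-defensin gene Defa24 stood at 2564 ± 3326 CPM in the controls and 3280 ± 494 CPM in the libraries labelled Klf5-KO. Reads that match several of the near-identical alpha-defensins could go uncounted. Without control replicate 3 the list's median was 2.40 (adjusted p = 4.1e-38, camera; adjusted p = 0.33 with an estimated correlation). The list was also called higher with limma-voom (median 1.20, adjusted p = 0.0074), with the replicate block (1.28, adjusted p = 0.0071) and with no low-count filter (0.41, adjusted p = 0.021). With an estimated correlation, none of these 3 calls held (adjusted p = 0.63, 0.77 and 0.73).

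**Figure D3:**
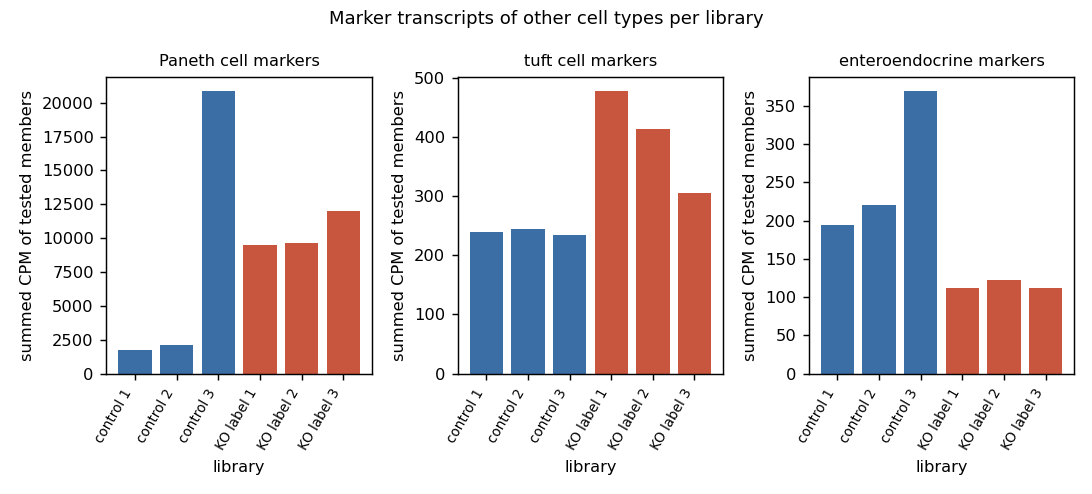
Summed normalised read counts (CPM) of the tested Paneth, tuft and enteroendocrine markers in each library, from 0, with 1 bar per library (blue, control; red, labelled Klf5-KO). Control replicate 3 holds 20839 CPM of Paneth transcripts against 1766 and 2131 in the other controls, while tuft markers lie between 305 and 477 CPM in the libraries labelled Klf5-KO and between 234 and 244 CPM in the controls.

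Lists of antimicrobial, interferon and MHC class II genes were called higher. Of 19 antimicrobial and epithelial defence genes, 13 rose and 2, Duox2 and Nos2, fell (15 and 2 adjusted over the list alone), with a median of 1.57 (adjusted p = 2.7e-06, camera; adjusted p = 0.43 with an estimated correlation). Besides Reg1, the lectin gene Reg3a and the adhesion molecule gene Icam1 rose 6.69-fold and 3.89-fold. Of 23 genes of the type I interferon response, 10 rose and none fell (12 and 0 adjusted over the list alone; median 0.55; adjusted p = 0.0032, camera; adjusted p = 0.74 with an estimated correlation), among them Ifit1, Ddx60 and Parp14 by 2.77, 1.18 and 0.93 on the log2 scale. Of 8 genes of MHC class II presentation, 2 rose, H2-DMa and H2-DMb1 (6 adjusted over the list alone; median 0.80; adjusted p = 0.035, camera; adjusted p = 0.75 with an estimated correlation). The summed CPM of the 8 class II genes was 1768, 704 and 1023 in control replicates 1, 2 and 3 and 1838, 2221 and 1967 in Klf5-KO replicates 1, 2 and 3, so that control replicate 1 stood near the lowest Klf5-KO value. The class II list was no longer called without control replicate 3 (adjusted p = 0.064) or Klf5-KO replicate 2 (0.097), nor with robust dispersion (0.082) or DESeq2 (0.17). The calls of H2-DMa and H2-DMb1 were each lost without control replicate 3 (adjusted p = 0.053 and 0.061) and without any 1 of the 3 Klf5-KO libraries (0.053 to 0.090).

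The lists of fatty acid oxidation and of cholesterol synthesis were called higher. Of 24 genes of fatty acid oxidation and PPAR targets, 10 rose and 1, Cpt2, fell (10 and 2 adjusted over the list alone; median 0.19; adjusted p = 2.7e-05, camera; adjusted p = 0.43 with an estimated correlation). The coactivator gene Ppargc1a rose from 10.4 ± 2.2 to 41.7 ± 2.9 CPM. Of 21 genes of cholesterol synthesis, 6 rose and none fell (7 and 0 adjusted over the list alone; median 0.16; adjusted p = 0.035, camera; adjusted p = 0.75 with an estimated correlation), with Idi1 and Cyp51 up by 0.96 and 0.57 on the log2 scale. The call for cholesterol synthesis was lost without control replicate 3 (adjusted p = 0.11) or Klf5-KO replicate 2 (0.097), and where CPM above 1 was required in 3 libraries (0.051).

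Epithelial junction and keratin genes fell. Of 30 tested, 16 fell and 3, Tjp1, Krt20 and Cldn2, rose (17 and 3 adjusted over the list alone), with a median of −0.31 (adjusted p = 2.4e-05, camera; adjusted p = 0.43 with an estimated correlation). The laminin gene Lamb3 fell from 50.5 ± 6.0 to 7.68 ± 1.37 CPM (log2 fold change −2.72, SE 0.15, adjusted p = 8.2e-06). Cldn15, a claudin of the small intestine, and Jup, the plakoglobin gene, fell, with log2 fold changes of −1.70 and −0.80.

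Transcription factors moved in both directions. Of 23 intestinal transcription factor genes, 11 rose and 5 fell (11 and 6 adjusted over the list alone; median 0.27; adjusted p = 0.20, camera). This list was called by fry (adjusted p = 0.0499), by camera with no low-count filter (0.044) and with control replicate 3 and Klf5-KO replicate 2 both left out (0.025). With an estimated correlation, camera's 2 calls of it were lost (adjusted p = 0.49 and 0.50). The homeobox gene Cdx1 fell 4.56-fold from 228 ± 14.7 CPM (log2 fold change −2.19, SE 0.08, adjusted p = 1.3e-06), while the bile acid receptor gene Nr1h4 and Hnf4g rose 3.28-fold and 2.67-fold. Of 21 other Kruppel-like and Sp factor genes, 5 fell and 3 rose (6 and 3 adjusted over the list alone; median −0.05; adjusted p = 0.81, camera). Klf3 and Klf13 fell, with log2 fold changes of −0.79 and −0.66, and Klf7 rose (1.01). Klf4, a factor of differentiated epithelium, stood at 134.5 ± 39.1 CPM in the controls and 117 ± 5.9 CPM in the libraries labelled Klf5-KO (adjusted p = 0.42).

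Genes of regeneration, the fetal-like state and YAP activity were not called as a list. Of 22 tested, 5 fell and 3 rose (6 and 7 adjusted over the list alone; median 0.15; adjusted p = 0.87, camera). Krt7 fell from 136 ± 17.9 to 28.7 ± 5.0 CPM, while Clu rose 6.30-fold; Ccn2 and Il33 were the others that rose. None of 22 genes of the unfolded protein response passed (median 0.04; adjusted p = 0.72, camera), and Calr stood at 692 ± 132 and 684 ± 33.7 CPM. Markers of other cells were low: in no library did the summed CPM exceed 40.5 for lymphocyte, 52.2 for myeloid, 13.7 for mesenchymal or 30.6 for endothelial markers, and none of these lists was called by camera, while fry called the endothelial list (adjusted p = 0.030). Of 5 neural and glial, 4 pancreatic acinar and 4 stomach markers, 3, 1 and 1 fell (4, 1 and 1 adjusted over the list alone), 1 stomach marker rose, and these lists were not called either (adjusted p = 0.096, 0.38 and 0.87, camera). Without control replicate 2 the neural and glial list was called lower (adjusted p = 0.038; adjusted p = 0.59 with an estimated correlation).

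Lists that bear on RNA quality and handling (mitochondrial, structural non-coding and immediate early) were not called by camera in the main analysis. Neither were the lists of ribosome biogenesis, p53 targets and the BMP and TGF-beta response, which were not chosen as signs of quality. Some of all these were called under alternatives. Of 13 mitochondrially encoded mRNAs 3 rose, mt-Nd1, mt-Nd2 and mt-Nd6, with the same count adjusted over the list alone (median 0.34; adjusted p = 0.061, camera), and mitochondrial mRNAs made up 1.97 to 2.69% of the counts in the controls and 2.98 to 3.35% in the libraries labelled Klf5-KO. With the GC and length correction their log2 fold changes were 0.10, 0.17 and −0.07, and none passed. The mitochondrial list was called higher with DESeq2 (adjusted p = 0.029), limma-voom (0.0072), no low-count filter (0.0044) and the sex covariate (0.033), and without control replicate 1 (0.0034) or Klf5-KO replicate 1 (0.012). With an estimated correlation, which was not run for DESeq2, the other 5 calls were lost (adjusted p = 0.61 to 0.76). Of 13 structural non-coding RNAs 1, Malat1, rose (median 0.31; adjusted p = 0.42, camera), and of 20 immediate early genes, which respond to dissociation, 2 rose, Klf6 and Nr4a1 (1 adjusted over the list alone; median 0.18; adjusted p = 0.46, camera). Without control replicate 3 the immediate early list was called (median 0.37, adjusted p = 0.011; adjusted p = 0.63 with an estimated correlation). Of 25 ribosome biogenesis genes 4 fell, Polr1b, Noc2l, Pes1 and Nolc1, and Utp20 rose, none of them adjusted over the list alone (median −0.19; adjusted p = 0.096, camera); without control replicate 3 or Klf5-KO replicate 2 the list was called (adjusted p = 0.0014 and 0.0068), as it was with limma-voom (0.011), with the replicate block (0.048) and with no low-count filter (0.049). With an estimated correlation, none of these 5 calls held (adjusted p = 0.63 to 0.84). Of 25 p53 targets and apoptosis genes 3 fell and 2 rose (median −0.15; adjusted p = 0.81, camera), and of 16 genes of the BMP and TGF-beta response 4 rose and 3 fell (5 and 3 adjusted over the list alone; median 0.13; adjusted p = 0.22, camera), a list called higher without control replicate 3 (adjusted p = 0.045; adjusted p = 0.50 with an estimated correlation). Bmp2 rose 3.18-fold and Id1, a target of BMP signalling, fell 1.88-fold.

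In all, 15 of 35 lists were called by camera with a preset correlation, 8 lower and 7 higher. None of the 15 calls held with an estimated correlation, where the smallest adjusted p was 0.43. The Notch list lost its call there though its estimated correlation, −0.0013, lay below the preset 0.01. There camera also takes its degrees of freedom from the few libraries, not from the number of genes, so calls are hard to reach. A lost call thus does not by itself show that the genes of a list move together, nor that the list did not move. Fry, which tests whether a list's genes move on balance in 1 direction, called 12 lists. Of these, 9 were among the 15, and 3, the reserve stem cell, endothelial and intestinal transcription factor lists, were called by fry alone. Camera's calls for the tuft, enterocyte, interferon, MHC class II, cholesterol and DNA replication lists were not shared by fry (adjusted p = 0.072 to 0.17). The gene-level p-values behind the counts of members that passed do not use a list's correlation. Members that vary together tend to pass or fail together, so such a count is not that many separate results.

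**Figure D4:**
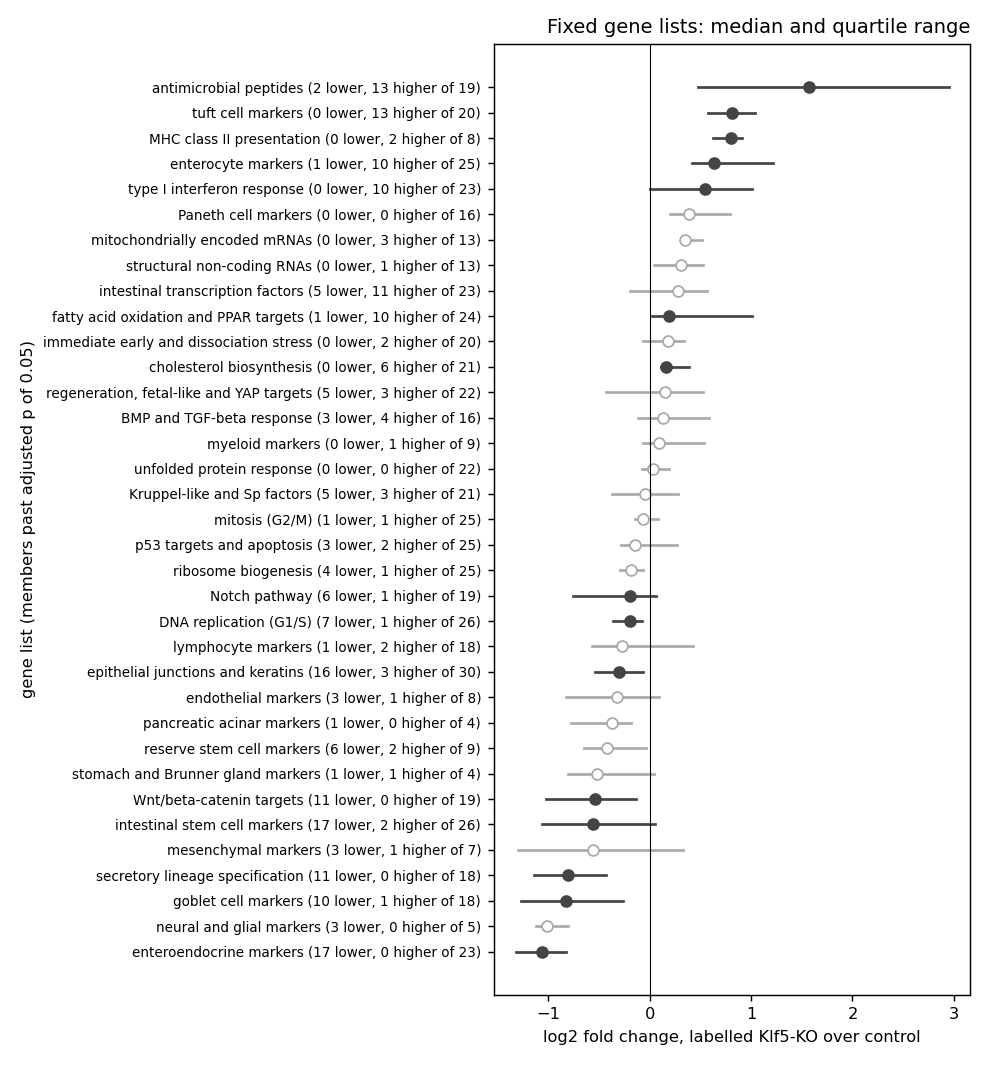
Median log2 fold change (points) and quartile range (lines) of the tested members of each of 35 gene lists, labelled Klf5-KO over control, with the number of lower and higher members at an adjusted p under 0.05. Filled points are the 15 lists called by camera with a preset correlation, from enteroendocrine markers at −1.06 to antimicrobial peptides at 1.57; none of them was called with an estimated correlation.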

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

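The alternatives with a GC and length correction, a sex covariate, without Gm26917 and Gm42418, and with 2 libraries left out were chosen after seeing the data. Klf5 stayed higher and past the threshold in all 19 alternatives, at log2 fold changes of 0.75 to 0.84. Leaving out 1 library gave 1605 to 2740 higher genes, 1467 to 2664 lower genes and 13 to 18 lists. All these fits have fewer libraries, but the counts also depended on which library was left out. Without control replicate 3, 2740 genes were higher and 2664 lower, above the 2581 and 2413 of the main fit. The number of genes higher in Klf5-KO was 1226 at an adjusted p under 0.01 and 709 in a test against a minimum fold change of 1.5, and the number of genes lower in Klf5-KO was 1118 and 692, both stricter by construction. With an estimated correlation 0 lists were called, against 15 with the preset one; fry called 12, of which 9 were among the 15. Of the 4994 calls, 3975 were kept with the GC and length correction and 4783 with DESeq2. Counting new calls too, the correction called 2306 genes higher and 2701 lower, and DESeq2 called 2819 higher and 2630 lower. The mt-Nd6 log2 fold change reversed under the GC and length correction, to −0.069 (adjusted p = 0.78); the cause was not tested. Over all alternatives, named genes lost their call in 112 comparisons, gained one in 6 and stayed on the same side of the threshold in 2017. In 1 comparison the sign changed for a gene called in either fit. Sign changes of genes called in neither fit were counted as staying. Lists lost a call in 13 comparisons, gained one in 25 and stayed in 623. The scalings moved the median of all genes by less than 0.1. The replicate numbers did not pair the libraries, as deviations from the group means correlated at −0.04 to 0.05 for all 9 pairs of a control and a Klf5-KO library; with the replicate block 2286 genes were higher, 2088 lower and 17 lists called, and Klf5 was at 0.80. Depth left counts of 0 uncertain only below 0.0484 CPM.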

Other observations

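Gene families, some with members on the fixed lists, also moved. Among 176 families of genes that share a symbol stem, 4 were higher and 1 lower by camera with a preset correlation, and none held with an estimated one (adjusted p = 0.98 for each). Of 22 keratin genes 16 were lower and 1 higher in the libraries labelled Klf5-KO (median log2 fold change −1.77). Of 13 UDP-glucuronosyltransferase genes 8 were higher and 0 lower (median 1.09), though reads from exons that these genes share can go uncounted. Of 12 acyl-CoA thioesterase genes 8 were higher and 2 lower, and of 66 histone genes 23 were higher and 1 lower. By biotype, 50 of 142 small nucleolar RNA genes were higher and 0 lower (median 0.71), 34 of 162 sense intronic genes were higher and 5 lower, 256 of 1170 genes of the provisional biotype TEC were higher and 55 lower (median 0.38), and 7 of 77 small nuclear RNA genes were higher and 0 lower. Antisense genes leaned the other way (58 higher, 97 lower of 759), and lincRNA genes went both ways (81 higher, 84 lower of 752). Over all tested genes, 2581 of 19339 were higher and 2413 lower. Small nuclear RNA genes were thus higher no more often than all genes, and antisense genes were lower about as often as all genes. Whether the share of nuclear or unspliced RNA differed between the groups was not tested. Genes that were higher had a median GC content of 46.2%, those lower 53.1% and the rest 49.3%.

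The tests below were chosen after the main results were seen. For the GC and length trend, the DNA around Klf5 and the splits of the libraries, the bounds were written before those tests were run.

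Klf5 was higher, not lower, in the libraries labelled Klf5-KO. Depth or scaling is argued against, since even without scaling the lowest Klf5-KO count was 1.49 times the highest control count, while the deepest library was a control, and so is an exchange of single libraries, since the lowest Klf5-KO CPM was 1.60 times the highest control CPM and the groups lay apart on the first principal component. Whether all 6 labels were exchanged, or reads came from parts of the gene that recombination leaves, cannot be told apart from whole-gene counts, as the lower group still had a mean of 513 CPM. Reads from the remaining parts could by themselves keep the count in place but not raise it. What would raise it, if the labels are right, was not tested. If the labels were exchanged, every direction given here would be turned round. Counts per exon would decide this.

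The stem cell list was lower in the libraries labelled Klf5-KO. A trend over GC content and gene length is argued against as the whole cause, since the median stayed at −0.58 after its removal, and so are abundant non-coding transcripts in the library size, which would move all genes of a library alike. In counts without any scaling, the list's median less that of all genes in the same library differed by −0.55 between the groups, and its lowest control value lay 0.33 above its highest Klf5-KO value. A factor per library cancels in this difference, so it restates the main result in another form and is not separate evidence. A lower share of stem cells in the sort, with every other type raised alike, would raise the markers of each type. Enteroendocrine markers had a median of −1.06 (17 of 23 lower) and tuft markers one of 0.82 (13 of 20 higher). These values argue against that form only, and not against a lower share with some types raised. The deletion of Klf5 stays open as a biological explanation, untested because of the Klf5 counts, and a shift within the sorted gate toward enterocyte or tuft cells stays open too.

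Paneth transcripts differed between the control libraries. In control replicate 3, 15 of 16 markers were over 2 times higher than in each other control, so carry-over of Paneth cells, neighbours of the stem cells that the gate on EGFP should remove, is not excluded. It stays open, since the high sum in this library was known when the markers were counted. Sex is argued against, since control replicate 3 stood at a median of 9.66 times control replicate 2 with the same sex markers. The libraries labelled Klf5-KO held 5.30 times the mean of control replicates 1 and 2 and 0.527 times control replicate 3, so the size of the group difference depends on control replicate 3. Whether the level in the libraries labelled Klf5-KO has the same source was not tested.

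Within 10 Mb of Klf5, 12 of 34 tested genes changed (35.3%) against 25.8% of the others, an odds ratio of 1.57 (95% interval 0.71 to 3.31; two-sided Fisher's exact p = 0.24). DNA of another strain around the floxed allele could raise that share, and these few genes do not decide it.

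The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split called 4994 genes (1 of the 10 splits reached that), and the highest other called 0 by edgeR. For lists, the real split called 15, the highest other 20, and 6 of the 10 splits, the real one included, called 15 or more. Other groupings of these libraries thus gave as many list calls with the preset correlation. Every other split mixes libraries of both groups in unequal numbers, so it still holds part of the group difference. That difference also widens the spread within its sets, which makes gene calls unlikely. The other splits are therefore no measure of what libraries without a group difference would give.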
